A study of Mus musculus with 12 samples.

How the data were processed

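The series measured gene expression in mouse embryonic stem cells on Affymetrix arrays of a single design. The cells were Tcf3+/+ (wild type) or Tcf3-/- (knockout). Per the labels they grew without feeder cells in serum medium with Lif, and RNA came from control medium or from medium with 50 ng/ml recombinant Wnt3a given for 24 h. Tcf3 in the labels is the older name of Tcf7l1, an HMG-box protein of the Tcf/Lef family that binds beta-catenin, and it is a different gene from the E2A gene now called Tcf3. The 4 groups of genotype and medium held 3 arrays each, 12 in all. The labels number the replicates and do not say whether they came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

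The authors deposited a single table of processed values for 45101 probe sets on the 12 arrays. RMA is named in the submitters' processing notes, with no version, and other settings are not given in the sources used here. The deposited values are intensities on a linear scale, with lowest values per array between 9.26 and 9.97 and highest between 30928 and 32765, and not on a log scale, so log2 was taken before any test and no pseudocount was added. Each array's lowest, highest and quartile values were close to those of the others. Median intensities per array ran from 71.6 to 73.4 on control-medium arrays and from 68.3 to 70.1 on Wnt3a arrays, without overlap. No detection calls and no scan dates were used here. The number of arrays, 3 per group, limits the precision.

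Probe sets were named from the platform annotation supplied with the table. Of the 45101 probe sets, 64 were array controls, 34945 carried 1 gene symbol, 932 carried several and were not used by name, and 9160 were not listed in the annotation and stay unnamed here. The 34945 probe sets covered 18193 genes, and 18032 of 18194 Entrez identifiers were found in the RefSeq table of assembly GRCm38.p6, which served only for names and for the chromosome of each gene. Each gene was represented by the probe set with the highest mean over the 12 arrays, and for the knockout effect in control medium 51 of 2075 genes with at least 2 called probe sets had called probe sets of opposite direction. A gene was kept if at least 3 of the 12 arrays lay above the 40th percentile of all values of probe sets that are not controls, which was 5.56 on the log2 scale or an intensity of 47.2. This left 13811 genes. With no detection calls, that level also served as a floor. Where a group's mean lay below it, the fold is given as a bound against the floor and written as at least N-fold.

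Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior) over all 12 arrays, so that the groups share an estimate of the spread. The 5 comparisons were the knockout effect in control medium, the Wnt3a effect in wild-type cells, the Wnt3a effect in knockout cells, the knockout effect in Wnt3a medium, and the interaction, which is the Wnt3a effect in knockout minus that in wild type. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and every adjusted p of a gene is limma's. The median standard error of a difference between 2 groups was 0.089 on the log2 scale. Lists were tested with camera (preset correlation 0.01), two-sided and adjusted over 25 lists per comparison, with camera at an estimated correlation and fry beside it. The 25 lists were fixed before the data were examined. They were general pluripotency, naive pluripotency, formative and primed epiblast, Wnt target genes, Wnt pathway components, primitive streak and mesoderm, endoderm, trophectoderm, neural ectoderm, Nodal and Activin, BMP, FGF and ERK, LIF and Stat3, 2-cell-like genes, germ cell genes, fibroblast and feeder markers, haematopoietic and endothelial markers, p53 targets, cell cycle, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and amino acid stress response, ribosomal proteins, imprinted genes, and adhesion and epithelial-mesenchymal genes. Of 635 list symbols, 49 were not matched. Some genes stand in several lists.

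The genes named in the text were taken by a rule fixed before the data were examined. For each pairwise comparison it took the 8 largest rises and the 8 largest falls among called genes whose arrays do not overlap, and from each list the 4 called members with the largest change and the 2 largest that did not pass. It also took the 8 largest interactions, the 8 genes with the largest change shared by the knockout and Wnt3a effects, and a fixed set of Wnt pathway and pluripotency genes in every comparison. RIKEN and predicted names were passed over. Part of these genes is printed below, and a gene outside the rule is said to have been chosen after its values were seen. Tcf7 and T, in the fixed set, were not matched under those names and are not analysed here.

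The fit was checked on simulated data over the same 13811 genes, with 200 genes changed. For the knockout effect in control medium it recovered 47 of 50 genes changed 1.5-fold and 50 of 50 changed 2-fold, and 1 of 50 changed 1.2-fold, with 7 false calls. For the interaction it recovered 27 of 50 at 1.5-fold and 48 of 50 at 2-fold, with 6 false calls. Camera found a list of 25 genes shifted by 0.2 on the log2 scale in 20 of 20 simulations of that comparison. Simulated genes were independent of each other, which real list members are not.

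Alternatives covered the probe set rule, the filter, rescaling of the arrays, the variance model, array weights, the arrays in the fit, a replicate block, stricter thresholds and leaving out each array. Correlations across genes were set beside 100 simulations of unchanged groups that share the same control arrays. Other splits of the samples were counted, all 10 for each pairwise comparison and 100 drawn for the interaction. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.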

Results

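Expression was measured in mouse embryonic stem cells with and without the Tcf3 gene (Tcf7l1), each in control medium and after 24 h with 50 ng/ml Wnt3a, a secreted ligand that stabilises beta-catenin. Each of the 4 groups had 3 arrays. Values below are deposited intensities on the log2 scale, changes are differences of group means with the standard error (SE) of the limma fit, and n = 3 arrays per group throughout. Within groups, arrays correlated across probe sets between 0.9923 and 0.9974. In a principal component analysis the first component held 64.1% of the variance and set wild-type arrays in control medium (-46.5 to -33.3) furthest from the knockout arrays (21.7 to 31.7). Wild-type arrays with Wnt3a lay between them (-21.9 to -4.6).

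The arrays of the 2 media differed in the control sequences added during preparation. Bacterial poly-A transcripts, which are spiked into RNA before labelling, were at background on all 6 control-medium arrays and clearly present on all 6 Wnt3a arrays. The dap transcript averaged 4.10 ± 0.04 (SD, n = 6) in control medium and 11.2 ± 0.10 in Wnt3a medium, a 138-fold difference, and thr differed by 4.45, phe by 3.19 and lys by 2.85 on the log2 scale. Spike-ins added at hybridization were also higher on Wnt3a arrays, bioB by 2.56 and cre by 1.82. Between genotypes within a medium the spike-ins differed less, dap by -0.02 and bioC by 0.32 in control medium, and dap by -0.17 and bioC by 0.24 in Wnt3a medium. Probe sets for 18S ribosomal RNA differed between genotypes by 0.44 in control medium and by -0.71 in Wnt3a medium, where wild-type arrays (10.43 to 10.85) and knockout arrays (9.51 to 10.27) did not overlap. Signs of RNA quality also moved with the groups, but only that of actin parted the genotypes in both media. The difference between 3' and 5' probe sets of Gapdh averaged 0.01 in wild type and 0.02 in knockout cells in control medium. With Wnt3a it averaged -0.09 and -0.06, and the arrays of the genotypes overlapped in each medium. The difference between 3' and 5' actin probe sets averaged 0.21 ± 0.03 (SD, n = 3) in wild type and 0.35 ± 0.06 in knockout cells in control medium, and 0.26 ± 0.02 and 0.38 ± 0.03 with Wnt3a, with no overlap of genotypes in either medium. That for Tfrc fell with Wnt3a, from a mean of 1.56 to 1.11 in wild type (1.51 to 1.65 against 1.08 to 1.14 on single arrays), and in knockout cells from a mean of 1.42 (1.25 to 1.62) to a range of 1.14 to 1.26, which overlaps it. Medium and sample preparation therefore cannot be told apart in this design, and each Wnt3a effect below is a difference between Wnt3a arrays and control arrays that includes it. Each knockout effect lies within 1 medium, where the spike-ins differed less than between media but some still parted the genotypes without overlap, as the actin 3'-5' differences did. These were cre in control medium (11.59 to 11.81 in wild type, 11.84 to 12.14 in knockout) and, with Wnt3a, dap (11.24 to 11.33 and 11.07 to 11.15), lys (7.29 to 7.34 and 6.96 to 7.24) and bioC (10.05 to 10.2 and 10.24 to 10.47). In the interaction only a difference in preparation that acts alike on both genotypes cancels, and 18S did not act alike, with an interaction of -1.15.

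**Figure D1:**
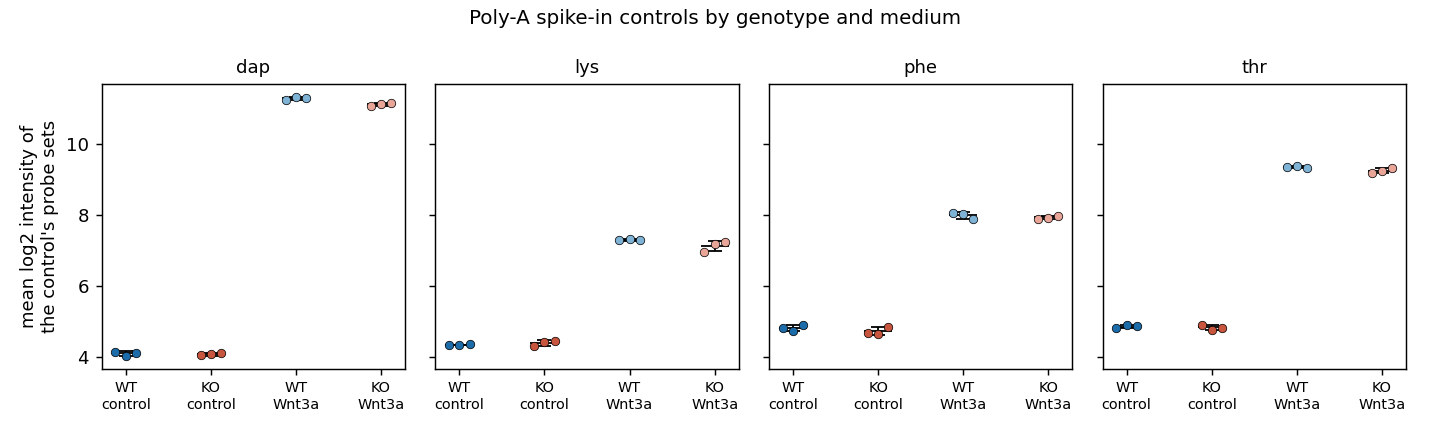
Mean log2 intensity of the probe sets of 4 poly-A spike-in transcripts on each array (points), with group mean and SD (bars, n = 3 arrays), by genotype (WT, KO) and medium. The dap transcript lay at 4.15 or below on all control-medium arrays and at 11.07 or above on all Wnt3a arrays.

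The targeted gene was lower in every knockout array than in every wild-type array of the same medium, but it was not near background. The brighter of 2 Tcf7l1 probe sets averaged 10.85 ± 0.07 (SD, n = 3) in wild type and 9.47 ± 0.11 in knockout cells in control medium, a 2.60-fold difference (log2 -1.38 ± 0.10 SE, limma adjusted p = 1.17e-06). With Wnt3a it averaged 10.37 ± 0.15 and 9.10 ± 0.18 (log2 -1.28). The second probe set was 3.39-fold lower in knockout cells in control medium and 3.47-fold lower with Wnt3a. Which exons were deleted is not given in the sources used here, so a probe set outside the deleted part may still read a transcript. Tcf7l1 was also lower on Wnt3a than on control arrays in wild type (log2 -0.47 for the first probe set and -0.48 for the second) and in knockout cells (-0.37 and -0.52), and the interaction did not pass for either. For the first probe set the difference in knockout cells lost its call without knockout control array 1 (adjusted p = 0.0728) or 3 (0.053) or knockout Wnt3a array 3 (0.0679).

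**Figure D2:**
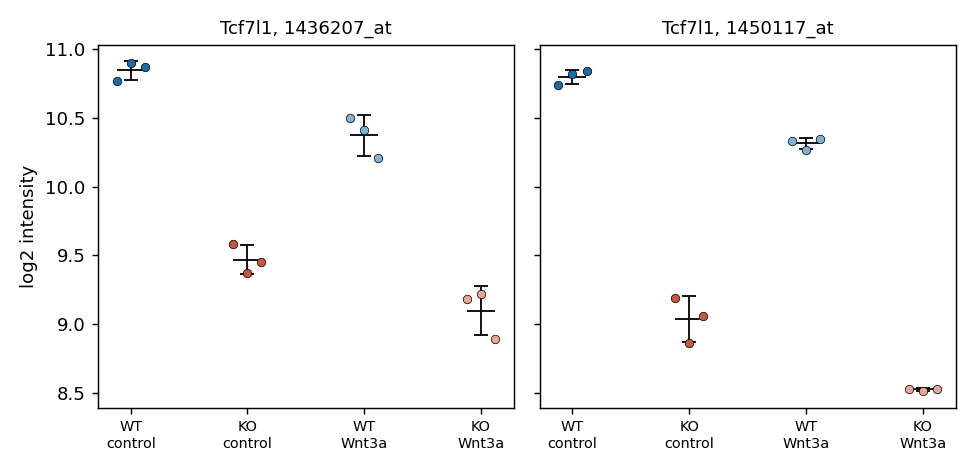
Log2 intensity of both Tcf7l1 probe sets on each array (points), with group mean and SD (bars, n = 3 arrays), by genotype and medium. All knockout arrays lie at 9.58 or below and all wild-type arrays at 10.21 or above.

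The knockout effect in control medium compares Tcf3 knockout with wild-type cells under standard self-renewal conditions. The array titles give the genotype but no cell line. Loss of Tcf3 therefore cannot be told apart here from other differences between the cells of the 2 genotypes, and this holds for every knockout effect below. Naive pluripotency genes, which mark the ground state of the early epiblast, were higher in knockout cells. Tagln, the actin gene Acta1 and the keratin genes Krt8, Krt18 and Krt19 were far lower, and trophectoderm markers fell as a list, by less. Of the 22 naive pluripotency genes tested, 19 rose and 2 fell, with a median log2 change of 1.04. Among them, Tbx3, a T-box factor of the naive network, rose 5.82-fold (log2 2.54 ± 0.17, limma adjusted p = 5.87e-07), with 3 of its 4 probe sets called. Manba rose 5.64-fold, and the transcription factor Tfcp2l1 rose 4.20-fold. Esrrb, an orphan nuclear receptor of the same network, rose 3.24-fold, Klf2 2.12-fold, Nanog 1.99-fold and Nr5a2 1.78-fold. Klf5 changed by 0.17 and did not pass (adjusted p = 0.0774, and 0.0477 without knockout Wnt3a array 3). Of 24 general pluripotency genes 15 rose and 1 fell. Foxd3 rose by 0.89 and Fgf4 by 0.77 on the log2 scale, whereas the core factors Pou5f1 (0.32) and Sox2 (0.35) rose by less. Adjusted over the list alone, 20 naive and 16 general pluripotency genes rose. Both lists passed camera (adjusted p = 1.14e-09 and 0.00041). With an estimated correlation the adjusted p was 0.303 for the naive and 0.388 for the general list. By fry, which tests no list against other genes, it was 1.13e-05 and 0.00114. The genotypes compared also differed in the actin 3'-5' difference, 0.21 against 0.35.

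Among the largest falls were those of Prss23, Tagln, Gbp2b, Krt18, Acta1, Cnn1, Krt8 and Krt19. Tagln, which encodes the actin-binding protein transgelin, was 44.9-fold lower in knockout cells (log2 -5.49 ± 0.22, limma adjusted p = 5.08e-08). The actin gene Acta1 was 28.1-fold lower, Acta2 16.9-fold lower and calponin gene Cnn1 22.3-fold lower, in cells whose actin 3'-5' difference was 0.35 against 0.21. Among epithelial keratins, Krt18 was 29.3-fold lower, Krt8 21.6-fold lower and Krt19 21.4-fold lower. The protease gene Prss23 was at least 22.6-fold lower and the interferon-inducible GTPase gene Gbp2b at least 25.1-fold lower, since their knockout means lay under the floor, so that these have no order among the others. Among the largest rises were the glutathione transferase gene Gsta3 (14.2-fold), Timm8a2 (at least 6.31-fold), Nlrp4f (6.55-fold), Xaf1 (6.28-fold), Myo1f (6.18-fold), Rcsd1 (6.02-fold) and the metal transporter gene Slc11a1 (5.76-fold). Rcsd1 had 3 probe sets, of which 1 was called higher.

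**Figure D3:**
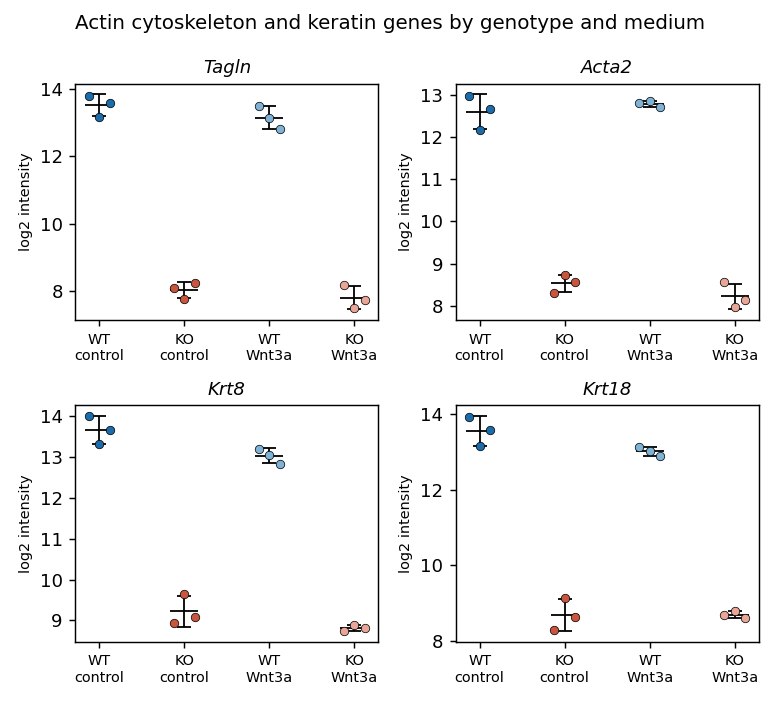
Log2 intensity of Tagln, Acta2, Krt8 and Krt18 on each array (points), with group mean and SD (bars, n = 3 arrays), by genotype and medium. Tagln averaged 13.52 in wild type and 8.03 in knockout cells in control medium, and 13.15 and 7.80 with Wnt3a.

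Trophectoderm markers fell in 11 of 20 cases and none rose (median log2 change -0.56, camera adjusted p = 0.000101). This was the only list that passed with an estimated correlation (adjusted p = 0.031). Besides Krt8 and Krt18, Krt7 was 9.82-fold lower and the homeobox gene Rhox6 fell by 1.59 on the log2 scale. Of 24 adhesion and epithelial-mesenchymal genes 16 fell and 4 rose (adjusted p = 0.000926, and 0.388 with an estimated correlation). The claudin genes Cldn7 (10.2-fold lower) and Cldn6 (5.85-fold lower), which encode tight junction proteins, led after the keratins. Fibroblast and feeder markers fell in 9 of 16 cases and rose in 4 (adjusted p = 0.00858, and 0.388 with an estimated correlation), a call lost with the stricter filter (0.176). The falls were led by Tagln, Acta2 and the caveolae gene Cav1 (log2 -2.59), while the abundant fibroblast genes Fn1 and Vim, chosen after their values were seen, passed narrowly in the other direction (log2 0.34 and 0.39, adjusted p = 0.0476 and 0.0359). Both calls were lost without wild-type control array 2 (0.182 and 0.138) or 3 (0.17 and 0.0686), or knockout control array 1 (0.145 and 0.0925), 2 (0.0861 and 0.0645) or 3 (0.0642 and 0.0802). That of Fn1 was also lost without wild-type Wnt3a array 1 (0.0574), 2 (0.0624) or 3 (0.0576) and knockout Wnt3a array 2 (0.0624) or 3 (0.0511). Of 20 BMP pathway genes 12 fell and 1 rose (adjusted p = 0.00125, and 0.303 with an estimated correlation). The BMP-responsive Id2 was 7.31-fold lower, Id1 2.62-fold lower and Bmp2 at least 2.01-fold lower, whereas Bmp4 changed by 0.29 (adjusted p = 0.135). Of these lists, 12 trophectoderm, 16 adhesion, 11 fibroblast and 13 BMP genes fell when adjusted over the list alone. The actin 3'-5' difference (0.21 against 0.35) moved with these groups too.

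Germ cell genes rose in 9 of 16 cases and fell in 2 (camera adjusted p = 0.0354, and 0.388 with an estimated correlation). The meiotic gene Hormad1 rose 4.67-fold, the RNA-binding protein gene Dazl 4.43-fold and the receptor gene Kit 2.74-fold. Of 21 glycolysis and hypoxia genes 8 rose and 1 fell (adjusted p = 0.00989, and 0.388 with an estimated correlation), led by the phosphofructokinase gene Pfkp at 4.41-fold and Bnip3 at 1.77-fold. The counts of both lists were the same when adjusted over the list alone. Without wild-type control array 1 the germ cell list had an adjusted p of 0.0604, and with the stricter filter 0.0816, and without wild-type control array 2 the glycolysis list had 0.0513.

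Several pathways had called members without passing as lists. In the FGF and ERK list 10 of 19 genes fell and 4 rose (median log2 change -0.45, camera adjusted p = 0.0539), with the ERK phosphatase gene Dusp4 5.64-fold and Phlda1 3.11-fold lower and the immediate-early gene Egr1 2.73-fold higher. That list passed without wild-type control array 3 (0.0475), knockout control array 3 (0.0367) or knockout Wnt3a array 1 (0.0401), 2 (0.0489) or 3 (0.0406). It also passed with the mean of all probe sets (0.0431), without the filter (0.0114), with median centring (0.0417) and after repeated quantile normalization (0.0379). In the formative and primed epiblast list 7 of 17 fell and 3 rose (median -0.34, adjusted p = 0.0647, and 0.0367 without knockout control array 3, 0.0328 with the mean of all probe sets and 0.0119 without the filter). Pou3f1 was 9.77-fold lower, Sox4 3.42-fold (5 of 6 probe sets called) and Sall2 3.33-fold, while Otx2 changed by -0.46 (adjusted p = 0.292). Wnt target genes went both ways, 5 higher and 10 lower of 26 (median -0.10, adjusted p = 0.318). The 5 include Esrrb, Nr5a2 and Tfcp2l1, which also stand in the naive list. Ccn4 was 5.04-fold lower, Cd44 at least 2.82-fold lower and Cdx1 2.53-fold higher, and the direct targets Axin2 (log2 0.15, adjusted p = 0.49) and Sp5 (-0.34, adjusted p = 0.32, and 0.0325 without wild-type control array 2) did not pass. Of 54 Wnt pathway components 8 were higher and 17 lower (median -0.07, adjusted p = 0.148). The lower members include Tcf7l1, the targeted gene itself. The ligand carrier gene Wls was at least 7.74-fold lower, Wnt4 7.15-fold lower and Tcf7l2 3.05-fold lower, the last called in 1 of 3 probe sets. Lef1 changed by -0.34 (adjusted p = 0.0945, and 0.00024 without knockout control array 3) and Ctnnb1 by 0.01 (adjusted p = 0.896, and 0.14 with adjusted p = 0.0393 for the mean of its 3 probe sets, of which 1 was called higher).

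In numbers, 2743 genes were higher and 3081 lower in knockout cells in control medium out of 13811 tested, of which 331 and 585 changed at least 2-fold. Of the 25 lists 8 passed camera.

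The knockout effect in Wnt3a medium makes the same comparison when the ligand is present. Tagln, Acta2, Krt8 and Krt18 were again far lower in knockout cells, trophectoderm markers fell as a list by less (median log2 change -0.48), and the rise of naive pluripotency genes was smaller. Tagln was 40.7-fold lower (log2 -5.35 ± 0.22, limma adjusted p = 8.46e-08), Acta2 23.8-fold, Krt18 20.1-fold, Krt8 18.6-fold and Acta1 16.9-fold lower. Prss23 was at least 12.6-fold, Gbp2b at least 18.8-fold and Gbp2 at least 12.5-fold lower. The rises were led by Timm8a2 (at least 6.18-fold), Efhc2 (5.73-fold), Slc11a1 (5.72-fold), the lysine catabolism gene Aass (5.67-fold), Xaf1 (5.43-fold), Uba1y (5.07-fold), Magea4 (at least 4.67-fold) and Egfl6 (at least 3.77-fold). The actin 3'-5' difference was 0.26 in wild type and 0.38 in knockout cells in this medium. In total 1828 genes were higher and 2035 lower, of which 123 and 300 changed at least 2-fold. Of the calls 47.3% were higher, and 56.6% after repeated quantile normalization.

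Of the 22 naive pluripotency genes, 8 rose and 2 fell in this medium (median log2 change 0.19, camera adjusted p = 0.0131, and 0.589 with an estimated correlation). By fry the list did not pass (adjusted p = 0.0918). Tbx3 rose 1.87-fold, Manba 2.60-fold, Esrrb 1.41-fold, Tfcp2l1 1.38-fold and Nanog 1.19-fold (limma adjusted p = 0.0238). Of the probe sets 3 of 4 were called for Tbx3 and 2 of 3 for Esrrb. Klf2 changed by 0.17 (adjusted p = 0.107), Nr5a2 by -0.16 (adjusted p = 0.333) and Sox2 by 0.05 (adjusted p = 0.722). Dppa3 was 3.64-fold and Fgfbp1 2.10-fold lower. In this medium 9 naive genes rose and 2 fell when adjusted over the list alone, between genotypes with actin 3'-5' differences of 0.26 and 0.38. The naive list lost its call without wild-type Wnt3a array 1 (adjusted p = 0.0799). Nanog lost its call without wild-type Wnt3a array 1 (0.0962) or 2 (0.0562), without knockout Wnt3a array 2 (0.0755) or 3 (0.0666), and with only the arrays compared (0.0557).

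Trophectoderm markers (11 of 20 lower, 1 higher, median -0.48) and the FGF and ERK list (11 of 19 lower, 4 higher, median -0.46) passed camera with adjusted p = 3.84e-05 and 0.000727, and with an estimated correlation at 0.0235 and 0.0439. Cdx2, the trophectoderm determinant, was 1.97-fold lower, Dusp4 3.04-fold lower and the receptor gene Fgfr2 2.38-fold lower. Wnt target genes were lower in knockout cells in this medium, 12 of 26 against 2 higher (median -0.30, adjusted p = 0.000727, and 0.0593 with an estimated correlation). Ccn4 was 2.98-fold and Ccnd1 1.63-fold lower, while Axin2 (log2 -0.20, adjusted p = 0.359), Sp5 (-0.62, adjusted p = 0.0924) and Cdx1 (0.43, adjusted p = 0.208) did not pass. Sp5 passed without wild-type control array 1 (adjusted p = 0.0109) or 2 (0.0346) and with only the arrays compared (0.0105). Wnt pathway components (15 of 54 lower, 7 higher, adjusted p = 0.0346, and 0.268 with an estimated correlation) included Tcf7l2, at least 1.98-fold lower and called in 1 of 3 probe sets. They also included Tcf7l1, the targeted gene, whose fall was fixed by the design. That list lost its call without wild-type Wnt3a array 2 (0.0679) or knockout Wnt3a array 2 (0.0705). BMP genes (6 of 20 lower, none higher, adjusted p = 0.00138, and 0.268 with an estimated correlation) were led by Id2, 6.15-fold lower. Adhesion genes fell in 14 of 24 cases (adjusted p = 3.84e-05, and 0.268 with an estimated correlation) and fibroblast markers in 7 of 16 (adjusted p = 0.00299, and 0.284 with an estimated correlation), the latter call being lost with the stricter filter (0.0578). Adjusted over the list alone, 12 trophectoderm, 13 FGF and ERK, 12 Wnt target, 16 Wnt component, 6 BMP, 16 adhesion and 7 fibroblast genes fell. The actin 3'-5' difference (0.26 against 0.38) moved with these groups too.

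The other lists that passed were higher. Germ cell genes rose in 7 of 16 cases (adjusted p = 0.00739, and 0.284 with an estimated correlation), with Dazl at 3.77-fold, and glycolysis genes in 9 of 21 (adjusted p = 0.00124, and 0.284 with an estimated correlation). Haematopoietic and endothelial markers rose in 2 of 8 cases, Cd68 at 3.11-fold and Tek at 1.65-fold (adjusted p = 0.0415, and 0.268 with an estimated correlation), a call lost without wild-type Wnt3a array 3 (0.0733) or knockout Wnt3a array 1 (0.0608). It was also lost with the mean of all probe sets (0.126), without the filter (0.188) and after repeated quantile normalization (0.0678). Of these lists, 8 germ cell, 11 glycolysis and 5 haematopoietic and endothelial genes rose when adjusted over the list alone, again with actin 3'-5' differences of 0.26 and 0.38. Across genes, the knockout effects in the 2 media, which share no arrays, correlated at r = 0.866, and 1313 genes were higher in both against 363 expected of independent lists. For genes lower in both the numbers were 1629 and 454. Genes are not independent replicates.

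The Wnt3a effect in wild-type cells asks how the ligand changes expression when Tcf3 is intact. Wnt target genes such as Cdx1 and Sp5 and most naive pluripotency genes were higher on Wnt3a than on control arrays. Cdx1, a homeobox gene, was 7.38-fold higher (log2 2.88 ± 0.24, limma adjusted p = 1.05e-05), Sp5 3.63-fold and Axin2, a feedback inhibitor of the pathway, 1.70-fold. The homeobox gene Nkx1-2 was at least 4.41-fold higher, called in 2 of 3 probe sets. As a list, Wnt targets did not pass camera: 10 of 26 rose, 5 fell, median 0.07 (camera adjusted p = 0.136), and 10 rose and 6 fell adjusted over the list alone. By fry, which tests no list against other genes, the list was higher (fry adjusted p = 0.00077). Its 10 higher members include Esrrb, Nr5a2 and Tfcp2l1, which also stand in the naive list. Notum changed by 0.39 (adjusted p = 0.0804), a value that passed without wild-type control array 2 (0.0333) or wild-type Wnt3a array 1 (0.0498) and with median centring (0.0433). Cdx2 changed by -0.24 (adjusted p = 0.278) and Lef1 by -0.02 (adjusted p = 0.939), with 1 of its 2 probe sets called higher, and Tcf7l2 was 1.91-fold lower (2 of 3 probe sets called). Ctnnb1 did not pass (adjusted p = 1), but 1 of its 3 probe sets was called higher, and the mean of the 3 gave 0.24 (adjusted p = 0.00287). All of these genes were compared between arrays that differed by 7.18 in dap and in the Tfrc 3'-5' difference (1.56 against 1.11).

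**Figure D4:**
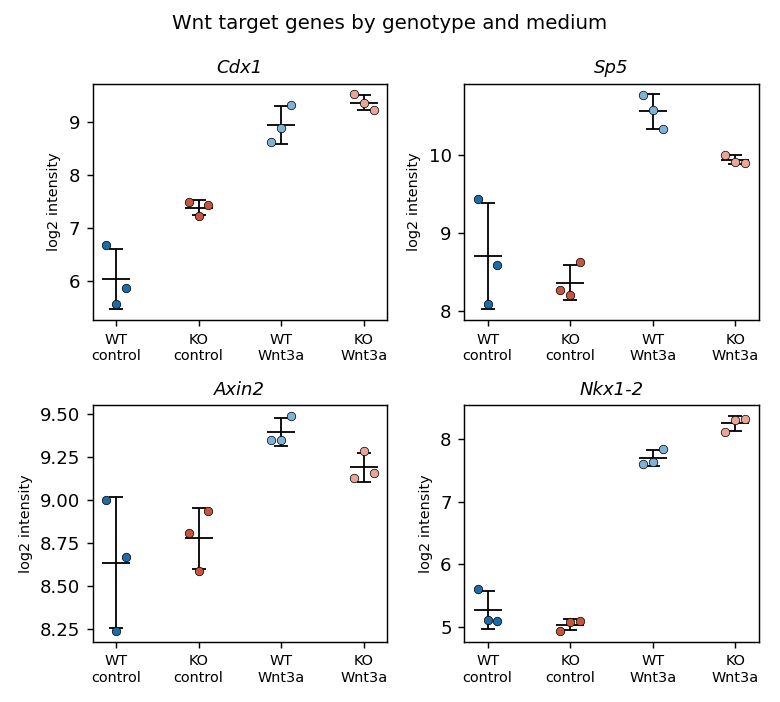
Log2 intensity of Cdx1, Sp5, Axin2 and Nkx1-2 on each array (points), with group mean and SD (bars, n = 3 arrays), by genotype and medium. Sp5 averaged 8.70 and 10.57 in wild type and 8.36 and 9.94 in knockout cells in control and Wnt3a medium.

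Of the 22 naive pluripotency genes 18 rose and none fell (median 0.88, camera adjusted p = 1.87e-11, and 0.407 with an estimated correlation). By fry the list passed (adjusted p = 0.000124). Tbx3 was 3.42-fold higher, Tfcp2l1 3.35-fold, Klf4 3.07-fold, Nr5a2 2.57-fold, Esrrb 2.48-fold, Nanog 1.86-fold and Klf2 1.41-fold. All 3 probe sets of Esrrb and of Nr5a2, both of Klf4 and 3 of 4 of Tbx3 were called higher, between arrays that differed by 7.18 in dap. General pluripotency genes rose in 10 of 24 cases and fell in 2 (adjusted p = 0.0208, and 0.564 with an estimated correlation), with Rex2 at 3.48-fold and Sox2 at 1.54-fold. Adjusted over the list alone, 19 naive genes rose, and 11 general pluripotency genes rose and 2 fell. The general list lost its call without wild-type control array 1 (0.0887), when quantile normalization was applied again (0.173) and with the stricter filter (0.0503).

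Cell cycle genes rose in 16 of 29 cases and fell in 1 (median 0.16, adjusted p = 0.000553, and 0.407 with an estimated correlation). Cyclin gene Ccnd2 was 2.63-fold and Cdc25a 1.58-fold higher, and all 6 Ccnd2 probe sets but only 1 of 2 for Cdc25a were called higher, on arrays with the same dap difference of 7.18. Repeated quantile normalization ended the call of the list (0.0771). Germ cell genes rose in 6 of 16 cases (adjusted p = 0.039, and 0.407 with an estimated correlation), with Kit at 3.94-fold and Dazl at 2.20-fold. Adhesion genes fell in 11 of 24 cases and rose in 1 (adjusted p = 0.0223, and 0.509 with an estimated correlation), with Cldn6 2.23-fold and Cldn7 2.20-fold lower. Without wild-type control array 1 the germ cell list had an adjusted p of 0.0887 and the adhesion list 0.0923. With the stricter filter they had 0.0504 and 0.0503, and the germ cell list lost its call with the mean of all probe sets (0.0506) and with median centring (0.0628). Adjusted over the list alone, 16 cell cycle genes rose and 2 fell, 6 germ cell genes rose and 2 fell, and 13 adhesion genes fell and 1 rose. Pou3f1 was 3.07-fold and Sall2 2.84-fold lower. Of the actin and keratin genes, Cnn1 (log2 -1.33, adjusted p = 0.00573), Krt19 (-0.90, 0.018), Krt8 (-0.63, 0.0203, in 3 of 3 probe sets) and Krt7 (-0.60, 0.0248) were lower. Without wild-type control array 1 Krt8 (0.0865), Krt7 (0.0857) and Krt19 (0.0767) lost their calls, as they did without wild-type Wnt3a array 3 (0.0729, 0.0513 and 0.0599). Krt8 and Krt7 also lost theirs without wild-type control array 3 (0.0534 and 0.0608), Krt7 without wild-type Wnt3a array 2 (0.083), and Krt7 and Krt19 with only the arrays compared (0.0642 and 0.0594). Acta1 changed by -0.51 (adjusted p = 0.171, and 0.0309 without wild-type control array 2), Acta2 by 0.19 (adjusted p = 0.46), Tagln by -0.37 (adjusted p = 0.189) and Krt18 by -0.54 (adjusted p = 0.0528, and 0.0134 without wild-type control array 2, 0.035 without knockout control array 1, 0.0254 without knockout control array 2, 0.0479 with all probe sets tested and 0.0434 after repeated quantile normalization).

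Other large rises were Gad1 (at least 5.08-fold), the nuclear RNA Malat1 (5.91-fold), Crxos (at least 2.79-fold), the guidance molecule gene Ntn1 (4.15-fold), Gsta3 (4.14-fold) and the Wnt-modifying enzyme gene Porcn (2.93-fold). Other large falls were Cryl1 (5.42-fold), Mfap3l (4.20-fold), Tmem54 (3.87-fold), Otx2 (3.86-fold), Marveld3 (3.49-fold), Max (3.46-fold), Cdh10 (at least 2.36-fold) and St6gal2 (at least 1.23-fold). Malat1 had 3 probe sets called higher and 3 called lower, Cryl1 had 1 each way, and Gsta3 had 1 of 2 called. In total 2615 genes were higher and 3118 lower, of which 101 and 168 changed at least 2-fold. Genes with at least 2 called probe sets disagreed in direction in 659 of 2292 cases (28.8%), against 51 of 2075 (2.5%) for the knockout effect in control medium (Fisher's exact test, two-sided, p = 1.32e-142). That test takes genes as independent, although a gene can stand in both counts and both comparisons share the wild-type control arrays. Its p therefore does not measure the spread between arrays. Of the calls 45.6% were higher, and 61.5% after each array was centred on its median, so the balance of higher and lower genes depends on the scaling.

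The Wnt3a effect in knockout cells asks which responses to the ligand remain without Tcf3. Cdx1 and Sp5 were higher on Wnt3a arrays here too, whereas naive pluripotency genes as a group were not. Cdx1 was 3.92-fold higher (log2 1.97 ± 0.24, limma adjusted p = 0.000265), Sp5 higher by 1.58 on the log2 scale and Nkx1-2 at least 6.47-fold higher, while Axin2 changed by 0.41 (adjusted p = 0.0644), a value that passed without wild-type control array 1 (0.0247) or 2 (0.0159), with median centring (0.0345) and with only the arrays compared (0.0228). Between these arrays dap differed by 7.04. Among the 26 Wnt targets 6 rose and 6 fell (median 0.02, camera adjusted p = 0.805), and 8 and 6 adjusted over the list alone. Of the 22 naive genes 5 rose, 3 fell and 14 did not pass (median 0.09, camera adjusted p = 0.511), the same numbers as adjusted over the list alone. Klf5 was 1.36-fold and Klf4 1.38-fold higher, Zfp57 1.95-fold, Dppa3 1.57-fold and Klf2 1.34-fold lower. Tbx3 (log2 0.13, adjusted p = 0.591), Esrrb (0.10, adjusted p = 0.523), Tfcp2l1 (0.15, adjusted p = 0.363) and Nanog (0.15, adjusted p = 0.143) did not pass. With median centring Nanog passed (0.0495), with the mean of all probe sets Tfcp2l1 passed (log2 0.25, adjusted p = 0.0115), and 1 of the 4 Tbx3 probe sets was called higher.

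The lists that passed camera in knockout cells were 2. FGF and ERK genes fell in 7 of 19 cases and rose in 1 (median -0.27, adjusted p = 0.0367, and 0.338 with an estimated correlation), with Dusp5 at -0.60 and Dusp6 at -0.59 on the log2 scale. Germ cell genes rose in 7 of 16 cases and fell in 1 (adjusted p = 0.0367, and 0.709 with an estimated correlation), with Dazl at 1.88-fold. When adjusted over the list alone, 9 FGF and ERK genes fell and 9 germ cell genes rose, between arrays that differed by 7.04 in dap. Both calls were lost without knockout control array 1 (adjusted p = 0.0534 each) or knockout Wnt3a array 1 (0.0752 each), and that of the FGF and ERK list with a replicate block (0.0501). Adhesion genes, 7 of 24 lower and none higher (median -0.24, adjusted p = 0.0612), and 8 lower adjusted over the list alone, did not pass. That list passed with the mean of all probe sets (0.0075), without the filter (0.0148), with median centring (0.028) and after repeated quantile normalization (0.0333). It also passed without knockout control array 3 (0.0342) or knockout Wnt3a array 2 (0.0442) or 3 (0.00744), between arrays that differed by 7.04 in dap. The other large rises were Malat1 (5.12-fold, 3 probe sets higher and 2 lower), Pglyrp1 (4.08-fold), Btla (3.48-fold), Gad1 (3.37-fold), Zc3h13 (3.34-fold) and Cux2 (3.07-fold). The largest falls were Cryl1 (4.60-fold, called in 1 of 4 probe sets), Max (3.90-fold), Esrp1 (3.46-fold), Rian (3.01-fold, with 2 probe sets lower and 1 higher), Otx2 (2.97-fold), Rhpn2 (2.79-fold), Rsph4a (at least 2.77-fold) and Aph1a (2.72-fold). Zc3h13 and Aph1a were called in 2 of 3 probe sets each. In total 1840 genes were higher and 2032 lower, 39 and 66 of them at least 2-fold. Without knockout control array 3 there were 1130 and 1263, and without knockout Wnt3a array 2 there were 1194 higher. Probe sets of a gene disagreed in 425 of 1478 cases (28.8%). Of the calls 47.5% were higher, and 66.3% after median centring.

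The interaction tests whether the difference between Wnt3a and control arrays is itself different in the 2 genotypes. Naive pluripotency genes responded less in knockout cells: 16 of 22 had an interaction below 0 and none above, with a median of -0.92 on the log2 scale (camera adjusted p = 4.81e-20, and 0.202 with an estimated correlation). By fry the list passed too (adjusted p = 0.00228). When adjusted over the list alone, 17 lay below 0. The interaction of 18S probe sets was -1.15, and that of dap -0.14. The interaction was -1.64 ± 0.24 (SE) for Tbx3 (limma adjusted p = 0.0065), -1.61 for Prdm14, -1.60 for Tfcp2l1, -1.20 for Esrrb, -0.99 for Nr5a2, -0.92 for Klf2 and -0.74 for Nanog. For the Wnt targets Cdx1 (-0.91, adjusted p = 0.147), Axin2 (-0.35, adjusted p = 0.388) and Sp5 (-0.28, adjusted p = 0.72) it did not pass, nor for Pou5f1 (-0.05) and Sox2 (-0.30, adjusted p = 0.161). Cdx1 passed without wild-type control array 1 (-1.23, adjusted p = 0.0345). Among genes with all 4 group means above the floor, Gsta3 (-2.23), Myo1f (-2.04), Ntn1 (-1.88) and Ccnd2 (-1.84) were among the largest. Rsph4a and St6gal2 each had 3 means under the floor, and with those set to the floor their interactions were -1.47 and 0.30. All 6 probe sets of Ccnd2, all 3 of Myo1f and of Nr5a2 and both of Ntn1 were called, but only 1 of 2 for Gsta3, 2 of 4 for Tbx3 and 2 of 3 for Esrrb. Myo1f lost its call without any of 5 arrays (adjusted p from 0.0506 to 0.0591): wild-type control 1 and 3, knockout control 1 and 3 and wild-type Wnt3a 2.

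**Figure D5:**
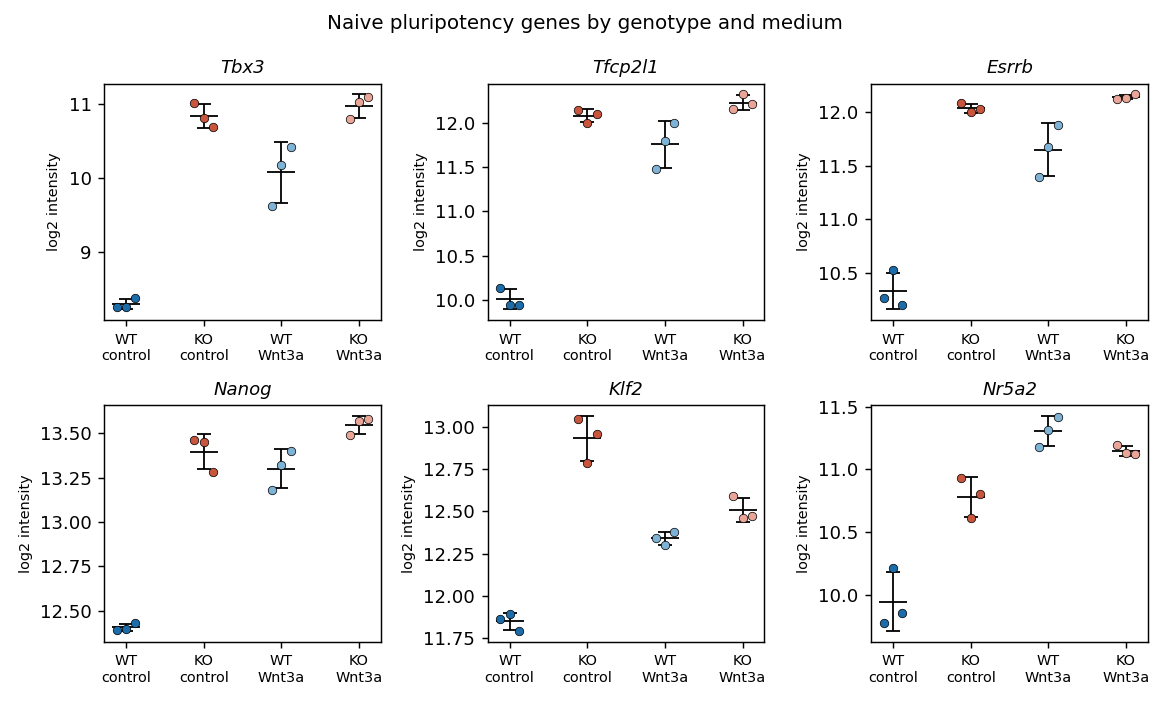
Log2 intensity of 6 naive pluripotency genes on each array (points), with group mean and SD (bars, n = 3 arrays), by genotype and medium. Tbx3 averaged 8.30 in wild type and 10.84 in knockout cells in control medium, and 10.07 and 10.97 with Wnt3a.

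The other 4 lists that passed had a negative interaction. General pluripotency had a median of -0.20 (adjusted p = 7.78e-05, and 0.639 with an estimated correlation). Cell cycle had -0.09 (adjusted p = 0.00278, and 0.658 with an estimated correlation), with Ccnd2 as its 1 called member. LIF and Stat3 genes had -0.21 (adjusted p = 0.0102, and 0.255 with an estimated correlation). The 2 called members of that list, Klf4 and Tfcp2l1, also stand in the naive list. Wnt target genes had -0.20 (adjusted p = 0.0183, and 0.255 with an estimated correlation), with Tfcp2l1, Esrrb and Nr5a2 from the naive list and Notum below 0 and Cd44 above (1.08 with its 2 means under the floor set to it), Notum and Cd44 being named after their values were seen. Adjusted over the list alone, 5 general pluripotency, 1 cell cycle, 4 LIF and Stat3 and 4 Wnt target genes lay below 0. The Wnt target list lost its call without wild-type control array 2 (0.105) or knockout control array 3 (0.0749) and with the mean of all probe sets (0.0924). The 18S interaction of -1.15 stands beside these lists too.

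In all, 304 genes had an interaction above 0 and 259 below, and the numbers depended on single arrays. Higher counts, listed here first, were 116 and 99 without wild-type control array 1, 67 and 84 without wild-type control array 3, 116 and 94 without knockout control array 1, and 109 and 106 without knockout control array 3. They were 81 and 99 without wild-type Wnt3a array 2, 116 and 116 without wild-type Wnt3a array 3, and 104 and 105 without knockout Wnt3a array 2. Without knockout control array 2 or knockout Wnt3a array 3 there were 196 and 183 above 0. The counts rose to 483 below 0 without wild-type control array 2 and to 568 above 0 without wild-type Wnt3a array 1. At an adjusted p under 0.01 there were 28 above and 48 below.

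The design also asks whether loss of Tcf3 and addition of Wnt3a change the same genes. In wild-type control cells as the common baseline, 1234 genes were higher both in knockout cells and with Wnt3a, against 519 expected of independent lists, and 1560 were lower in both, against 696. Only 182 were higher in knockout and lower with Wnt3a (619 expected), and 133 the reverse (583 expected). Genes with a large shared change were Gsta3, Ntn1, Tbx3 and Tfcp2l1, higher in both, and Mfap3l, Tmem54 and Marveld3, lower in both. St6gal2 was lower in both too, but its lower means lay under the floor, so it has no rank here. In knockout cells in control medium Ntn1 was 3.99-fold higher, Mfap3l 5.53-fold lower, Tmem54 4.59-fold lower, Marveld3 at least 5.18-fold lower and St6gal2 at least 1.23-fold lower. Across genes the 2 effects correlated at r = 0.559. They share the 3 wild-type control arrays, and unchanged groups simulated against these gave r = 0.501. Those groups held no real change, so their r is not a share of the observed one. The covariance was 0.1117 against a simulated 0.0057. By covariance, independent noise of the shared control arrays thus accounts for a small part of the relation. A deviation common to all 3 of these arrays would enter both effects and was not simulated. With 3 control arrays no split of these into 2 parts of at least 2 arrays was possible. How many of the shared calls come from the shared controls was therefore not measured.

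Wnt3a responses of the 2 genotypes, which share no arrays but the same contrast of preparations, correlated at r = 0.643, with 1195 genes higher in both (348 expected) and 1315 lower in both (459 expected). Without knockout control array 3 the lower count was 859, and median centring gave 1858 higher and 793 lower, so the balance of these depends on the scaling. Of the 2615 genes higher with Wnt3a in wild type, 195 had a smaller or opposite response in knockout cells by the interaction test. A larger response was found for 5. For the 3118 lower genes the numbers were 264 and 2. Smaller, here and below, includes responses of opposite direction. Among the 259 genes with an interaction below 0, 233 were higher in knockout cells in control medium and 177 of these were also higher with Wnt3a in wild type. Among the 304 above 0, 284 were lower in knockout cells and 249 of these were also lower with Wnt3a in wild type. With Wnt3a in knockout cells, 95 of the 259 were called lower and 30 higher. Of the 304, 83 were called higher there and 25 lower. The interaction shares its arrays with both effects, so these counts are tied to each other by construction. The sum of smaller responses, 459, depended on single arrays. It was 182 without wild-type control array 1, 123 without wild-type control array 3, 175 and 185 without knockout control arrays 1 and 3, and 150 and 185 without wild-type Wnt3a arrays 2 and 3. It was 179 and 304 without knockout Wnt3a arrays 2 and 3, and higher without wild-type control array 2 (761) or wild-type Wnt3a array 1 (771).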

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

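The tests of the Wnt target list as a sign of Wnt3a itself and of the levels of fibroblast genes were chosen only after their results were seen. The other tests of explanations were set down before, without the bootstrap intervals and the look into the larger interaction splits given below.

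Responses to Wnt3a that differed between the genotypes, by the interaction test, were found for 304 genes above 0 and 259 below. Among named genes the interaction (log2, knockout minus wild-type response) was below 0 for naive pluripotency genes: Tbx3 -1.64, Prdm14 -1.61, Tfcp2l1 -1.60, Esrrb -1.20, Klf4 -1.15, Manba -1.12, Dppa3 -1.11, Nr5a2 -0.99, Tcl1 -0.93, Klf2 -0.92, Zfp57 -0.75 and Nanog -0.74. It was also below 0 for Gsta3 (-2.23), Myo1f (-2.04), Ntn1 (-1.88), Ccnd2 (-1.84), Rsph4a (-1.73), Kit (-1.41), Porcn (-1.37), Notum (-1.07), Rex2 (-0.84) and Pfkp (-0.82). It was above 0 for St6gal2 (1.63), Cdh10 (1.56), Cd44 (1.51), Marveld3 (1.48), Mfap3l (1.45), Wnt4 (1.38), Cav1 (1.18), Sall2 (1.10), Dusp4 (0.89), Nkx1-2 (0.79), Id1 (0.74), Fosl1 (0.55) and Meg3 (0.42). Some of these values rest on group means under the floor and have no order among the others. With such means set to the floor the interaction was -1.47 for Rsph4a, 0.30 for St6gal2, 1.24 for Cdh10, 1.08 for Cd44, 1.80 for Marveld3, 1.83 for Mfap3l, 0.55 for Nkx1-2 and 0.74 for Fosl1. The interaction was called in 1 of 2 probe sets for Gsta3 and Mfap3l, 2 of 4 for Tbx3, 2 of 3 for Esrrb, 1 of 3 for Nkx1-2 and 1 of 11 for Meg3. The median interaction was -0.92 for the naive list, -0.21 for LIF and Stat3, -0.20 for general pluripotency and for Wnt targets, and -0.09 for cell cycle. Of 100 splits of the medium labels within each genotype, 6 gave as many genes as the real 563, the real split included, and the highest other gave 2900. The 5 larger splits kept all 6 wild-type arrays in their own medium and only 2 of the 6 knockout arrays, which lets the difference between media shared by both genotypes enter the interaction. They point to that structure of the samples, and so do not tell whether chance can be excluded for the count. The rule set down before took 5 or more of 100 splits as favouring chance, and 6 reached the real number. The look at which arrays the larger splits kept was added to that rule.

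For the pairwise comparisons, 10 splits of 6 arrays are too few for a share under 0.05. The real split was the 1 with the most genes in each. It gave 5824 for the knockout effect in control medium, 5733 for Wnt3a in wild type, 3872 for Wnt3a in knockout and 3863 for the knockout effect in Wnt3a medium, and the highest other gave 0 in each.

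Signals outside the main measurement separated the media. Wnt3a arrays were higher than control arrays by 7.11 (dap), 4.45 (thr), 3.19 (phe) and 2.85 (lys) for spike-ins added before labelling, and by 2.56 (bioB), 2.55 (bioC), 2.58 (bioD) and 1.82 (cre) for those added at hybridization. Probe sets for 18S ribosomal RNA were higher by 1.31, by 1.88 in wild type and 0.73 in knockout cells.

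The first pattern is the set of changes between control and Wnt3a arrays shared by both genotypes. Separate preparation of the control and Wnt3a arrays may account for part of it: called probe sets of a gene went opposite ways in 28.8% of genes for Wnt3a in wild type against 2.5% for the knockout effect in control medium. For Wnt3a itself, the fixed Wnt target list gave a camera p of 0.0598 in wild type and 0.708 in knockout, although Cdx1 and Sp5 rose in both. That neither shows nor excludes a shared response of the cells, since members went both ways. Medium and preparation cannot be told apart for these genes.

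The second pattern, noticed in the data, is the fall of actin cytoskeleton and keratin genes in knockout cells (median -4.46 for 8 named genes). Against fibroblast-like cells in the wild-type cultures as its whole cause stand a median of only -0.41 (95% bootstrap interval -0.77 to 0.27) for the fibroblast list without Tagln and Acta2, with 7 of 14 genes lower and 4 higher, among them Fn1 and Vim, and levels 5.71 below those of the 8 genes in wild type (interval 3.97 to 7.22), with Postn at 6.01, Dcn at 6.35 and Col1a2 at 7.36 beside 13.52 for Tagln. That interval reaches just past the limit set, 4, and most of the list lies near the floor, so such cells stay open. Trophectoderm-like cells stay open as well: without Krt7, Krt8 and Krt18 that list had a median of -0.36 (interval -0.94 to -0.08), with 8 of 17 genes lower and none higher. The rule set down before asked only for the median, and by it both medians, -0.41 and -0.36, would have argued against such cells. The intervals were added to that rule and reached below its limit, so both kinds of cells are left open here. All intervals given for this pattern came from resampling genes. They measure the spread between genes, which are not independent, and not the spread between arrays. As a hypothesis from the same data, a shared programme of actin genes driven by SRF, the serum response factor, that differs with genotype may be an explanation. Its list had a median of -1.38 (interval -1.67 to -0.58), with 20 of 23 members lower and 1, Egr1 (1.45), higher (camera p = 2.94e-11, and p = 0.0267 with an estimated correlation). Many members, such as Tpm1, Myl9 and Cald1, are actin cytoskeleton genes, so the fall of the list partly restates the pattern. The list holds no keratin gene and says nothing on that part of the pattern.

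The third pattern is that X-linked genes stood among the largest knockout differences. An extra or missing X chromosome in most of the cells is argued against, since X-linked genes had a median knockout effect 0.006 below that of autosomal genes (-0.006). An extra or missing autosome in most of the cells is argued against as well, since the largest shift of an autosome's median that both media shared was 0.051 in size. Chromosomes 1 (-0.058 in control and -0.051 in Wnt3a medium) and 8 (-0.041 and -0.074) had the lowest shifts in both media. A change carried by only a part of the cells could give shifts this small and stays open. Neither test covers a change of part of a chromosome.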

How the results depend on the processing

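The additive fit and the count of agreeing probe sets were chosen after seeing the data. Values after a slash are genes lower, and values before it genes higher.

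Away from leaving out arrays, named genes kept direction and side of the threshold in 2675 cases, gained a call in 35, lost it in 44 and reversed in 1. That 1 was Ctnnb1 for Wnt3a in wild type, 0.239 with the mean of its probe sets, 1 of which was called higher. Lists kept their call in 228 cases, stayed without one in 781, gained one in 55 and lost it in 51. With all probe sets tested, a larger number of units, the counts were 4681/4881 for the knockout effect in control medium, 5379/5409 for Wnt3a in wild type, 3885/3820 for Wnt3a in knockout, 2799/3487 for the knockout effect in Wnt3a medium and 458/557 for the interaction. The overlap of knockout and Wnt3a was then 2271/2441, and the responses shared by the genotypes 2828/2455, with r = 0.726 and 854 smaller in knockout. Median centring moved the shared responses to 1858/793, and the cause was not tested. Array weights did not converge and ran from 0.28 to 33.37, so that single arrays dominated, and their counts are given only for completeness. They were 4737 higher for the knockout effect in control medium, 5108/5743, 4187/4434, 4877/4780 and 3718/3459 for the other comparisons in the order above, 2846/3085 for the overlap and 2907/3166 for shared responses, with 5049 smaller in knockout. For changes of at least 1.5-fold, a stricter demand, the counts were 857/1286, 469/835, 194/404, 405/724 and 187/143, the overlap 209/472, shared responses 106/214 and 202 smaller. At an adjusted p under 0.01 they were 1619/1852 for Wnt3a in wild type, 913/971 for Wnt3a in knockout, 934/1204 for the knockout effect in Wnt3a medium and 28/48 for the interaction, with an overlap of 710/896, shared responses 585/572 and 67 smaller.

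Lists that passed, in the same order of comparisons, were 1, 0, 0, 2 and 0 with an estimated correlation. By fry, which tests no list against other genes, they were 19 for the knockout effect in control medium, 18 for Wnt3a in wild type and 4 for Wnt3a in knockout. Without the filter 13 passed for the knockout effect in control medium, and for Wnt3a in wild type 2 passed with a stricter filter and 3 after repeated quantile normalization. With array weights 0 passed for Wnt3a in knockout. The cause was not tested. The additive fit of genotype and medium gave 2991/3299 for the knockout effect, from all 12 arrays. Among genes with at least 2 called probe sets that all point 1 way, a smaller set by construction, Wnt3a gave 896/737 in wild type and 583/470 in knockout.

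The replicate numbers did not pair the arrays: of 18 pairs of same-numbered arrays 4 correlated over 0.1 (r from -0.257 to 0.244), and 4 of 12 arrays were closest to their own number. With a replicate block the counts were 2623/2977, 2474/3000, 1663/1890, 1682/1940 and 221/173, and 1 list passed for Wnt3a in knockout, FGF and ERK having an adjusted p of 0.0501. Of the genes named, Nr5a2 for Wnt3a in knockout (0.0515) and Fn1 for the knockout effect in control medium (0.0561) lost their call under the block.

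Leaving out each array in turn gave 2192 to 2828 higher and 2586 to 3141 lower for the knockout effect in control medium, 1924 to 2691 and 2335 to 3230 for Wnt3a in wild type, 1130 to 1911 and 1263 to 2118 for Wnt3a in knockout, 1264 to 1889 and 1462 to 2085 for the knockout effect in Wnt3a medium, and 67 to 568 and 84 to 483 for the interaction. The overlap ran from 862 to 1388 and 1124 to 1654 (r from 0.483 to 0.618), and shared responses from 817 to 1199 and 859 to 1255 (r from 0.597 to 0.675), with 123 to 771 smaller. Lists that passed ran from 7 to 11, 2 to 6, 0 to 3, 10 to 13 and 4 to 8. Tcf7l1 ran from -1.436 to -1.33 and -1.358 to -1.171 for the knockout effects in control and Wnt3a medium, -0.534 to -0.389 for Wnt3a in wild type and -0.432 to -0.263 for Wnt3a in knockout. None of these omissions reversed a called gene. Genes near background are limited by the floor at an intensity of 47.2.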

Other observations

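The genes and chromosomes singled out here were chosen after their values were seen, and no explanation is offered for them.

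Imprinted genes, expressed from 1 parental copy, went both ways in knockout cells in control medium, 6 higher and 12 lower of 23 (median -0.45, camera adjusted p = 0.107, and 0.0439 without the filter). The growth factor gene Igf2 fell by 2.82 on the log2 scale, the cell cycle inhibitor gene Cdkn1c by 2.46, Nnat by 1.78 and Gnas by 1.73, whereas the noncoding RNAs Meg3 (0.67), Rian (1.05) and Mirg (1.09) rose. With Wnt3a, Igf2 fell by 3.03 and Cdkn1c by 2.39 in knockout against wild-type cells. Among p53 targets 10 of 19 were lower and 3 higher in control medium (median -0.26, adjusted p = 0.0626, and 0.0405 or 0.0443 without knockout Wnt3a array 1 or 3, 0.0431 with the mean of all probe sets, 0.0187 without the filter and 0.0403 after repeated quantile normalization), with Perp at -2.19, Plk2 at -1.86 and Cdkn1a at -0.70. Cholesterol synthesis genes were lower in 7 of 20 cases and higher in 1 (median -0.17, adjusted p = 0.0626, and 0.0209 or 0.0342 without knockout Wnt3a array 1 or 3, 0.0239 without the filter and 0.0403 after repeated quantile normalization). Some lists passed for another comparison only in other settings. For Wnt3a in knockout these were endoderm without knockout control array 2 (0.000118) and cholesterol synthesis without knockout Wnt3a array 1 (0.000753). For the interaction cholesterol synthesis passed without that array (0.000183) and endoderm without knockout control array 1 (0.0156), 2-cell-like genes without the filter (0.0354) or knockout Wnt3a array 1 (0.0264), imprinted genes without wild-type control array 2 (0.0246) and p53 targets without knockout Wnt3a array 1 (0.0471). For Wnt3a in wild type haematopoietic and endothelial markers passed with median centring (0.0468) and without wild-type Wnt3a array 2 (0.0465) or 3 (0.0489) or knockout Wnt3a array 1 (0.0364) or 2 (0.049). In that comparison fibroblast markers passed without wild-type control array 2 (0.0322), 2-cell-like genes without knockout Wnt3a array 3 (0.0474) and formative genes without the filter (0.0492). For the knockout effect in Wnt3a medium formative genes passed without the filter (0.0424) and, without knockout Wnt3a array 3, p53 targets (0.0328) and cholesterol synthesis (0.042). Among actin-related genes, Tpm1 fell by 3.22 and Myl9 by 2.96, and Cald1 changed by -2.78, with 4 of its 5 probe sets called lower.

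The remaining lists did not pass for the knockout effect in control medium. Primitive streak and mesoderm had 2 higher and 3 lower of 19, with a median of 0.05 and a mean of -0.06. Endoderm had 3 and 3 of 23, with a median of 0.13 and a mean of -0.04. Neural ectoderm had 1 and 6 of 19 (median -0.08), Nodal and Activin 4 and 8 of 19 (median -0.16), LIF and Stat3 9 and 5 of 20 (median 0.15), and 2-cell-like genes 1 and 0 of 5 (median 0.34). The unfolded protein and amino acid stress response had 4 and 6 of 23, with a median of 0.05 and a mean of -0.07. Ribosomal proteins had 0 and 1 of 21, with a median of 0.02 and a mean of -0.02. Cell cycle had 7 and 2 of 29 (median 0.08), and haematopoietic and endothelial markers 2 and 1 of 8 (median 0.09).

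The Y-linked gene Uba1y averaged 6.99 in wild type and 9.51 in knockout cells in control medium, and 7.04 and 9.38 with Wnt3a, while the Y-linked Eif2s3y averaged 9.84, 10.13, 9.98 and 10.04 for wild-type and knockout control and wild-type and knockout Wnt3a. On chromosome 8, 104 genes were higher and 200 lower in knockout cells in control medium, and 46 and 153 with Wnt3a. On chromosome 1 the numbers were 121 and 229, and 70 and 182.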
